A study of Mus musculus with 10 samples.

How the data were processed

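Both experiments on mouse liver hepatocytes were analysed separately, because their counts were deposited in separately made tables. The authors deposited whole-number read counts per gene in both, as 6 per-sample tables for the diet experiment and 1 table for the EP300 experiment. Per the labels, liver cells were sorted after perfusion and libraries were made with a TruSeq RNA kit, which does not mark strand. The submitters' processing notes name STAR, HTSeq, DESeq2 and the build mm10, with no role for any of them. The annotation the authors counted against is not given in the sources used here, and neither is the strand setting behind the EP300 table. The per-sample tables have an unstranded and 2 stranded count columns and 4 rows for reads that were not counted to a gene. Those rows were left out of library sizes and tests, and the unmapped row alone held 98.2% to 99.2% of a library's reads. The EP300 table holds 4 further columns that match no sample, and these were not used here.

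In the EP300 table, 55144 of 55385 identifiers matched a gene symbol, and coordinates come from GENCODE M21 on the same build. In the per-sample tables, 0 of 57820 identifiers matched the mouse annotation, and 57773 have the form ENSG followed by a digit where the mouse annotation has ENSMUSG. No other annotation was tried, so fixed gene lists, named genes and the comparison of diet-changed genes with the EP300 experiment were not run for the diet experiment. The processing notes name mm10, but these identifiers leave open which genome and annotation the per-sample counts rest on, and with it what the unmapped share and every count of the diet experiment measure. Where so small a share of reads is counted, counts rest on what happened to align, and the levels need not represent the whole of a library.

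Groups and replicate numbers were taken from sample titles. Raw counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr with a minimum count of 10, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Only the libraries of a comparison entered its fit, which left 4 residual degrees of freedom in the diet experiment and 2 in the EP300 experiment. Standard errors are the absolute log2 fold change divided by the square root of F. The common biological coefficient of variation was 39.9% in the diet experiment and 5.47% in the EP300 experiment. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Camera compares a list with the other genes, whereas fry tests a list against no change, so their calls answer different questions. The 31 lists were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. CPM values are counts scaled to the TMM-adjusted library size. A gene with 0 counts in a group was compared with a floor of 3 counts over the group, and one with 1 to 3 counts by an exact binomial interval, as were Mup14 and Hsd3b5 with 6. Such intervals, and the Wilson intervals of shares, are at the 95% level and cover counting error only. Setting members with 3 or fewer counts in a group to that floor left the medians of the 3 lists that hold such members at -1.58, 2.86 and -1.68.

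Named genes were Ep300 and Met, and the 5 largest rises and 5 largest falls among genes that passed, whose groups did not overlap, whose mean was at least 10 CPM in the higher group and whose symbol was not a predicted or clone-based model. Added were the passing members with the largest changes, 3 of each primary list and 2 of each other list that was called or had at least 33.3% of its members pass. The rule took 71 genes, and not all of them are printed. Any pair of libraries of a label that agreed within sampling noise would have been counted as 1, and none did, since the lowest chi-square per degree of freedom within a label was 1.69. The median log2 fold change over all genes of the EP300 experiment was -0.01 with TMM, -0.00 with DESeq2 size factors (DESeq2 1.42.0) and -0.07 with library size alone.

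Alternatives were DESeq2, limma-voom, other scalings and filters, the stranded columns, a 2-fold threshold, the 20 most abundant genes left out, the replicate number as a block, and each library left out in turn. Their effects are given in the closing section.

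The tests were tried on simulated counts with 50 genes changed at each of 4 fold sizes. For the EP300 design edgeR recovered 64%, 72%, 98% and 100% of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold, with 12 false calls among 13953 genes tested. For the diet design it recovered 0%, 12%, 54% and 96%, with 7 false calls among 1944 tested. Camera with the preset correlation called 5 of 5 shifted lists in the EP300 design and with an estimated correlation 0 of 5, and neither called any of 20 unchanged lists. Simulated genes varied independently, so this does not show how often the preset calls unchanged lists of correlated genes. The correlation estimated in the data reached 0.55, in the male-biased list.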

Results

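RNA was sequenced from mouse liver hepatocytes in 10 libraries that fall into 4 groups. In 1 experiment, mice carrying cMet, a receptor tyrosine kinase gene delivered to the liver by tail vein injection of a plasmid, ate a normal diet (Met, 3 libraries) or a diet with DDC, a compound that injures hepatocytes and bile ducts (DDC+Met, 3 libraries), for 5 months. In the other experiment, mice with a floxed gene for EP300, a histone acetyltransferase and transcriptional coactivator, received DDC and cMet together with a hepatocyte-directed virus carrying Cre (EP300 KO, 2 libraries) or a fluorescent protein (EP300 WT, 2 libraries). Total counts per library in the EP300 experiment were 18575701 and 18831671 in EP300 WT and 17709799 and 17811489 in EP300 KO. In the diet experiment, 116010, 299002 and 306998 reads were counted to genes in Met replicates 1, 2 and 3, and 358269, 151777 and 153524 in DDC+Met replicates 1, 2 and 3. The labels mention pooled sequencing and do not tie a library to an animal. The p-values of genes and identifiers therefore measure only the spread between these libraries, which may be technical. Camera p-values set the genes of a list against the other genes. At the preset correlation they treat genes as nearly independent units, so a small value does not measure agreement between libraries. The permutation p-value of X-linked genes, given further on, also rests on genes as units.

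The EP300 comparison asks what loss of EP300 in hepatocytes changes in livers exposed to DDC and cMet. The titles of its libraries begin with HCC, an abbreviation of hepatocellular carcinoma, and those of the diet libraries with Liver. How much tumour each library held was not measured. The targeted gene was examined first. Ep300 (chromosome 15, 81585351 to 81652077, mm10) stood at 60.1 ± 3.15 CPM (counts scaled to a common library size, SD, n = 2) in the WT-labelled libraries and at 73.0 ± 1.00 (SD, n = 2) in the KO-labelled libraries, a log2 fold change of 0.28 (SE 0.07, edgeR adjusted p = 0.00498). It did not pass without EP300 WT replicate 2 (adjusted p = 0.128). The gene-level count was therefore higher, not lower, in the libraries labelled EP300 KO, and it cannot show whether an exon was deleted. Every direction below is drawn between libraries as labelled. Of the 10 histone acetyltransferases tested, Ep300 was the 1 that passed, also when adjusted over the list alone. Crebbp, the closest relative of Ep300 and named here after its values were seen, had a log2 fold change of -0.02 (adjusted p = 0.904). The mouse gene Met had a log2 fold change of 0.05 (adjusted p = 0.681). Whether reads of the injected cMet count towards it is not known here, so this value does not give the level of the plasmid gene.

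In the libraries labelled EP300 KO, 16 of 22 genes of bile acid metabolism, 12 of 16 of the periportal zone of the liver lobule and 13 of 13 of the male liver programme rose. In the same libraries, 12 of 18 markers of fetal liver and liver tumours, 26 of 31 cell cycle genes and 14 of 17 genes of the pericentral zone fell. Camera called these 6 lists at its preset correlation and 0 of them with an estimated correlation (adjusted p = 0.297 to 0.319), and 4 of the lists also held members that went the other way. In the simulation the estimated correlation also called 0 of 5 shifted lists. The simulated shift was smaller than the medians, given further on, of the male-biased, fetal, cell cycle and pericentral lists. The simulation therefore does not show whether this setting could call lists of that size, and it does not set the lack of calls aside. Of 14200 genes tested, 4851 changed at an adjusted p below 0.05 with edgeR's quasi-likelihood test, 2366 higher and 2485 lower. Of these, 1159 changed at least 2-fold, 448 higher and 711 lower. The largest falls by the fixed rule were in Adcy1, an adenylate cyclase (-4.30, SE 0.12), Cyp3a16 (-3.80, SE 0.20), the imprinted noncoding RNA H19 (chromosome 7, 142575529 to 142578143; -3.58, SE 0.10), the antiviral gene Rsad2 (-3.53, SE 0.11) and Ocstamp (-3.43, SE 0.13), all log2 fold changes. The 5 largest rises were all major urinary protein genes on chromosome 4. Mup7 (60066469 to 60070475) had 147714 counts in the KO-labelled and 2 in the WT-labelled libraries, both in replicate 2, a ratio of 81431 (95% counting interval 22542 to 672411). Its log2 fold change ran from 15.2 to 19.2 with a library left out. Mup11, Mup1 and Mup19 had 0 counts in the WT-labelled libraries and were at least 1132-fold, 745-fold and 542-fold higher, against a floor of 3 counts over the group. Mup14 had 48501 counts in the KO-labelled and 6 in the WT-labelled libraries, a ratio of 8912 (95% counting interval 4094 to 24287). These genes are near-identical copies that can share reads, so how the rise divides among them is uncertain.

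**Figure D1:**
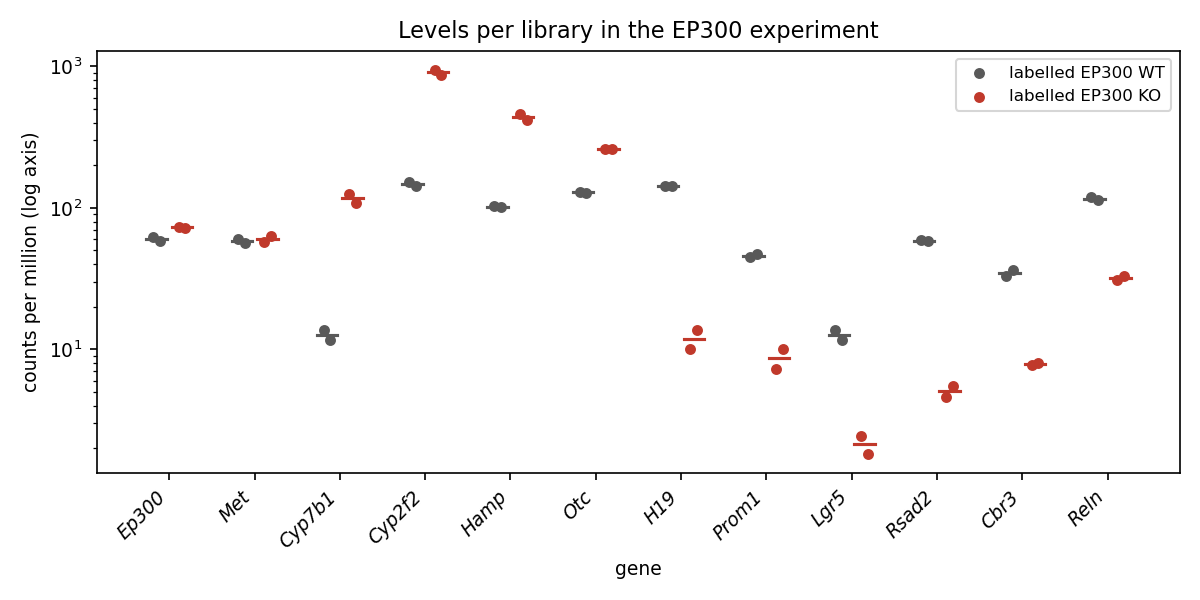
Levels in CPM (log axis) of 12 genes in each library of the EP300 experiment, with 1 point per library and a bar at the mean of the 2 libraries of a label. Ep300 lies slightly higher in the KO-labelled libraries (73.0 against 60.1), while H19 lies at 142 in the WT-labelled and 11.9 in the KO-labelled libraries.

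Hepatocyte genes moved modestly and, by number of genes, mostly upward. Of 30 hepatocyte identity and secreted protein genes, 16 rose and 4 fell (17 and 5 adjusted over the list alone), with a median log2 fold change of 0.17, or 0.11 under library size scaling. The list was called by camera (adjusted p = 0.00340, and adjusted p = 0.319 with an estimated correlation). Otc, a urea cycle enzyme, rose by 1.02 (SE 0.06), and Tdo2, which degrades tryptophan, by 0.94 (SE 0.06), whereas Apoa1, an apolipoprotein, fell by 0.67 (SE 0.05). The other members that fell, named after their values were seen, were Alb (-0.11), Trf (-0.58) and Ahsg (-0.50). Together with Apoa1 they had the highest levels of the list in the WT-labelled libraries, with Alb at 78219 CPM. Of 22 bile acid synthesis and transport genes, 16 rose and 2 fell, the same counts as adjusted over the list alone (median 0.37, camera adjusted p = 1.61e-11, and adjusted p = 0.319 with an estimated correlation). The uptake transporter Slco1a1 rose by 7.52 (SE 0.17) and Cyp7b1, an oxysterol hydroxylase, by 3.20 (SE 0.10). Both are also on the list of male-biased liver genes. Abcc4, an export pump, fell by 1.57 (SE 0.08).

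Zonal genes moved in opposite directions. Of 17 pericentral genes, 14 fell and 2 rose, also when adjusted over the list alone (median -1.21, camera adjusted p = 2.81e-18, and adjusted p = 0.306 with an estimated correlation). Sp5 fell by 2.88 (SE 0.38) and Lgr5 fell by 2.56 (SE 0.19). Both are targets of Wnt signalling. The 2 members that rose, named after their values were seen, were Cyp2e1 (0.30) and Cyp1a2 (0.19). Of 16 periportal genes, 12 rose and 1 fell, also when adjusted over the list alone (median 0.43, camera adjusted p = 1.59e-10, and adjusted p = 0.306 with an estimated correlation). Cyp2f2 rose by 2.62 (SE 0.06) and Hal, which degrades histidine, by 1.15 (SE 0.06). The Cyp2f2 value includes reads that an overlapping gene may share, since 13.5% of its exon bases overlap another gene.

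Fetal and tumour genes and the cell cycle fell. Of 18 fetal liver and liver tumour markers, 12 fell and 2 rose, also when adjusted over the list alone (median -1.58, camera adjusted p = 1.23e-21, and adjusted p = 0.297 with an estimated correlation). Besides H19, the growth regulator Dlk1 had 1 count in the KO-labelled libraries, in replicate 1, and 46 in the WT-labelled libraries, a ratio of 0.0240 (95% counting interval 0.000594 to 0.140). Its log2 fold change ran from -7.48 to -4.22 with a library left out. The 2 members that rose were Gpc1, a heparan sulfate proteoglycan (0.98, SE 0.20), with 18.9% of its exon bases shared with another gene, and the transcription factor Myc (0.65), named after its values were seen. Afp (-2.77, SE 0.11) and Gpc3 (-3.24, SE 0.11), used clinically as markers of liver cancer, also fell and are named here after their values were seen. Of 31 cell cycle genes, 26 fell and 0 rose (28 and 0 adjusted over the list alone, median -1.29, camera adjusted p = 2.74e-08, and adjusted p = 0.297 with an estimated correlation). The falls were -2.40 (SE 0.47) in Nusap1, -2.25 (SE 0.51) in Bub1 and -2.18 (SE 0.33) in Ube2c, all at low counts and with 22.8% of the exon bases of Ube2c shared with another gene. Without EP300 WT replicate 2, Nusap1 (adjusted p = 0.0533) and Bub1 (adjusted p = 0.0519) did not pass. Markers of some other cell types fell in the same libraries, as given further on.

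Camera called the biliary, YAP, NRF2 and immediate early lists downward, each with members that rose. Of 24 biliary and progenitor markers, 10 fell and 3 rose (12 and 3 adjusted over the list alone, median -0.36, camera adjusted p = 0.000574, and adjusted p = 0.425 with an estimated correlation). Tff3 changed by -2.40 (SE 0.12) and Prom1 by -2.40 (SE 0.12), while Cldn4, a tight junction protein, rose by 1.28 (SE 0.18). The median of this list was -0.54 without EP300 KO replicate 2. Of 23 YAP and TEAD targets, 9 fell and 5 rose, also when adjusted over the list alone (median -0.34, camera adjusted p = 0.0149, and adjusted p = 0.319 with an estimated correlation). Igfbp3 fell by 1.83 (SE 0.10) and Gadd45a rose by 1.20 (SE 0.19), with 19.1% of the exon bases of Gadd45a shared with another gene. The call of this list ended without EP300 KO replicate 2 (adjusted p = 0.0626). Of 20 NRF2 and glutathione genes, 17 fell and 2 rose, also when adjusted over the list alone (median -0.45, camera adjusted p = 1.58e-08, and adjusted p = 0.319 with an estimated correlation), with Cbr3 at -2.12 (SE 0.11) and Slc7a11, the cystine transporter, at -1.92 (SE 0.12). Of 18 immediate early genes, 8 fell and 2 rose, also when adjusted over the list alone (median -0.18, camera adjusted p = 0.0238, and adjusted p = 0.453 with an estimated correlation). Ier3 fell by 1.65 (SE 0.09). The camera call of the immediate early list ended without EP300 KO replicate 1 (median -0.18). Fry, which tests a list against no change, did not call it (adjusted p = 0.0699).

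Among inflammatory lists, 13 of 20 interferon response genes fell and 0 rose (14 and 1 adjusted over the list alone, median -0.80, camera adjusted p = 4.37e-07, and adjusted p = 0.319 with an estimated correlation). Besides Rsad2, the chemokine Cxcl10 fell by 2.80 (SE 0.18). Of 21 acute phase and NF-kB targets, 12 fell and 3 rose, also when adjusted over the list alone (median -0.30, camera adjusted p = 0.00438, and adjusted p = 0.451 with an estimated correlation). Apcs fell by 1.36 (SE 0.06) and Cxcl1 fell by 1.13 (SE 0.07).

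Among metabolic lists, 13 of 20 drug-metabolizing cytochromes and transferases rose and 4 fell (13 and 5 adjusted over the list alone, median 0.34, camera adjusted p = 1.92e-06, and adjusted p = 0.362 with an estimated correlation). Ugt2b1 rose by 2.32 (SE 0.08) and Cyp2c54 by 2.02 (SE 0.09). Of 16 fatty acid synthesis genes, 8 rose and 5 fell, also when adjusted over the list alone (median 0.11, camera adjusted p = 0.00623, and adjusted p = 0.465 with an estimated correlation). Thrsp rose by 2.69 (SE 0.07) and Pnpla3, a lipid droplet protein, fell by 1.54 (SE 0.34). The median of the list was 0.04 under library size scaling. Its call ended without EP300 KO replicate 1 (adjusted p = 0.0688) and without a filter, and that of Pnpla3 without EP300 WT replicate 1 (adjusted p = 0.0730) and without a filter. The lists of heme and iron handling (7 rose and 4 fell of 18, camera adjusted p = 0.0837), fatty acid oxidation (12 and 4 of 21; 0.0542), cholesterol synthesis (5 and 9 of 19; 0.128), glycolysis and hypoxia (5 and 8 of 18; 0.246), the unfolded protein response (8 and 8 of 18; 0.445), p53 targets (2 and 3 of 16; 0.246) and the Notch pathway (1 and 2 of 14; 0.299) were not called. Fatty acid oxidation was called in 5 of 10 alternatives, among them without EP300 KO replicate 1 (adjusted p = 0.0353) and without EP300 KO replicate 2 (adjusted p = 0.00722). Within these lists, Hamp, the iron hormone hepcidin, rose by 2.10 (SE 0.06), Alas1 by 0.84 (SE 0.06) and Acot1 by 1.78 (SE 0.11). Fgf21 changed by -2.65 (SE 0.18), Phgdh by -2.62 (SE 0.17) and Psat1 by -2.04 (SE 0.14).

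Sex-biased genes changed strongly. All 13 male-biased liver genes rose, also when adjusted over the list alone (median 2.86, camera adjusted p = 1.54e-67, and adjusted p = 0.297 with an estimated correlation). Elovl3 had 451 counts in the KO-labelled and 1 in the WT-labelled libraries, in replicate 2, a ratio of 497 (95% counting interval 88.8 to 19683). Its log2 fold change ran from 7.79 to 10.9 with a library left out. Hsd3b5 had 1466 counts in the KO-labelled and 6 in the WT-labelled libraries, a ratio of 269 (95% counting interval 123 to 735). Of 14 female-biased genes, 11 fell and 3 rose, also when adjusted over the list alone (median -1.68, camera adjusted p = 8.93e-10, and adjusted p = 0.319 with an estimated correlation). Hao2 had 2 counts in the KO-labelled libraries, both in replicate 2, and 118 in the WT-labelled libraries, a ratio of 0.0187 (95% counting interval 0.00224 to 0.0690). Sult2a1 went against its list and rose by 5.48 (SE 0.29). Xist, the noncoding RNA that silences an X chromosome in females, is named after its values were seen. It had 2310 and 1411 counts in the KO-labelled and 3 and 2 in the WT-labelled libraries.

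Markers of other cell types moved unevenly. Of 19 endothelial markers, 12 fell and 0 rose (12 and 1 adjusted over the list alone, median -0.28, camera adjusted p = 0.00726, and adjusted p = 0.453 with an estimated correlation), with Vwf at -1.23 (SE 0.11). Of 19 stellate cell and fibroblast markers, 8 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.26, camera adjusted p = 0.00726, and adjusted p = 0.362 with an estimated correlation), with Reln at -1.86 (SE 0.07) and Fbln2 at -1.94 (SE 0.29). The stellate median was -0.44 without EP300 KO replicate 1. Of 5 erythroid markers, 2 rose, also when adjusted over the list alone (median 0.28, camera adjusted p = 0.00365, and adjusted p = 0.359 with an estimated correlation), namely the heme synthesis gene Alas2 (2.85, SE 0.10, with 15.5% of exon bases shared with another gene) and Klf1 (1.22, SE 0.26). The erythroid median was 0.75 without EP300 WT replicate 1, 0.56 without EP300 WT replicate 2, 0.10 without EP300 KO replicate 1, 0.45 without EP300 KO replicate 2 and -0.04 without a filter. The list's call ended without EP300 KO replicate 1 (adjusted p = 0.0688) and without a filter, and that of Klf1 without EP300 WT replicate 2 (adjusted p just above the threshold) and without a filter. The 21 macrophage markers were not called (5 rose, 6 fell, camera adjusted p = 0.638), and their median of -0.00 and mean of 0.13 differed in sign. Marco, a scavenger receptor, rose by 2.59 (SE 0.17) and Gpnmb by 1.35 (SE 0.08). Lymphocyte (1 rose and 4 fell of 6; 0.129), neutrophil (0 and 5 of 10; 0.0745) and mesothelial markers (0 and 1 of 3; 0.445) were not called. Neutrophil markers were called in 5 of 10 alternatives, among them without EP300 WT replicate 1 (adjusted p = 0.0362) and without EP300 KO replicate 1 (adjusted p = 0.0159, median -1.15). Ighm, the constant region of IgM, fell by 1.74 (SE 0.19) and Ngp fell by 2.82 (SE 0.32).

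**Figure D2:**
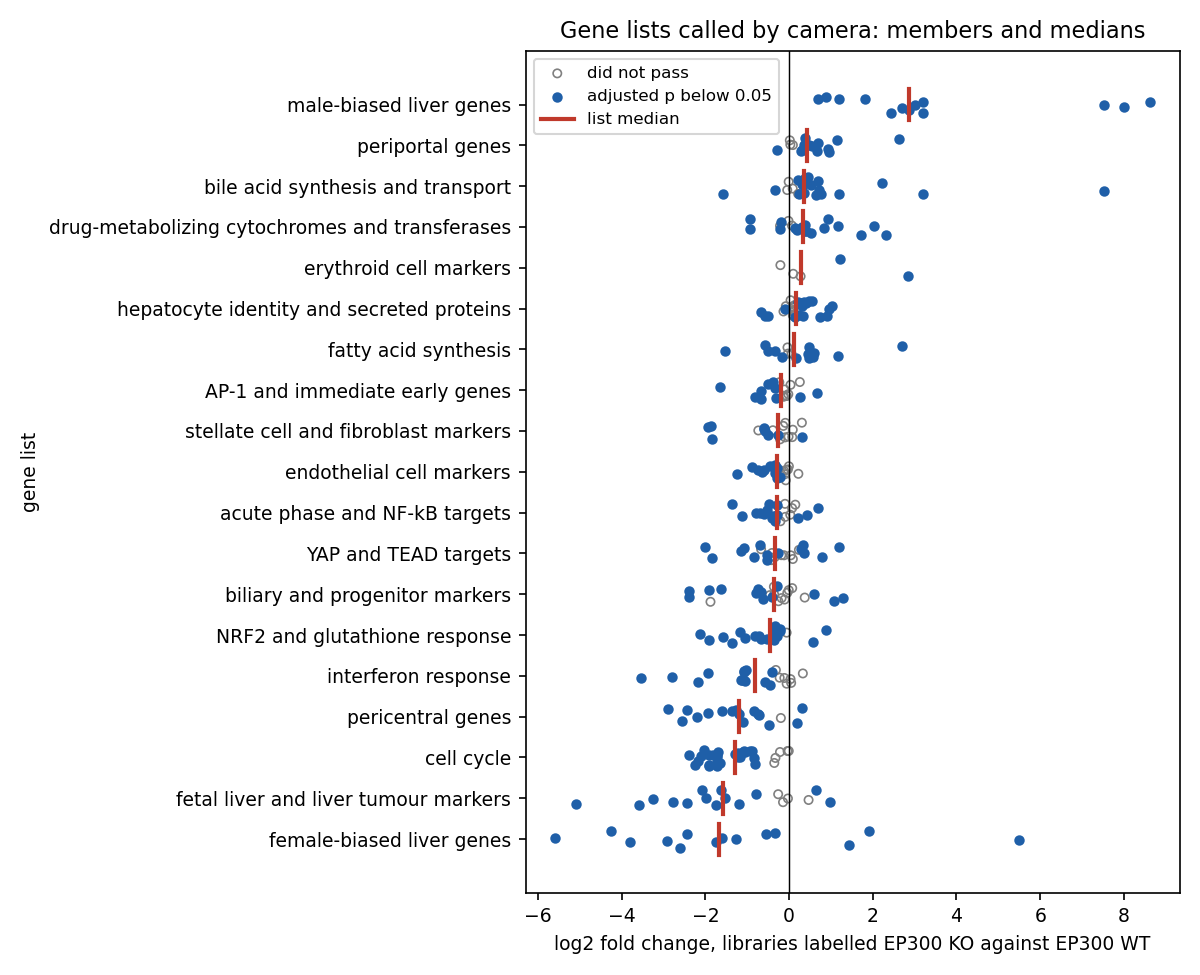
Log2 fold changes of the members of the 19 gene lists called by camera, with 1 point per gene (filled where the adjusted p was below 0.05) and a bar at each list's median. Medians run from -1.68 for female-biased liver genes to 2.86 for male-biased liver genes.

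Camera called 19 of the 31 lists, 7 upward and 12 downward. With a correlation estimated from the data it called 0, as it did of 5 shifted lists in the simulation. The simulated shift was smaller than several of the list medians. The number of changed genes fell to 2602 without EP300 WT replicate 1, to 2306 without EP300 WT replicate 2 and to 2937 with DESeq2, and under library size scaling the share of higher genes among the calls was 37.7% in place of 48.8%.

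The diet comparison asks what DDC adds to cMet. Its tables hold 57820 gene identifiers, of which 57773 begin with ENSG and a digit and 0 matched the mouse annotation used here, whose identifiers begin with ENSMUSG. The files do not pair them with names, so no gene or gene list is named, and which genome the reads were aligned to is not settled by the sources used here. Between 98.2% and 99.2% of the reads of a library were listed as unmapped, and 0.554% to 1.37% were counted to a gene. Of 2066 identifiers tested, 1 changed at an adjusted p below 0.05 with edgeR's quasi-likelihood test and 227 had an unadjusted p below 0.05. The identifier ENSG00000198355.4 fell by 2.87 on the log2 scale (SE 0.27, adjusted p = 0.0129), from 930 ± 97.9 CPM (SD, n = 3) in Met to 126 ± 25.7 (SD, n = 3) in DDC+Met, with every DDC+Met library below every Met library. It rested on 89, 298 and 290 counts in Met and 53, 19 and 14 in DDC+Met. The groups did not overlap for 16.5% of the identifiers, where chance gives 10%. DESeq2 called 31 identifiers and limma-voom 5. The count was 74 without Met replicate 1, 2 without DDC+Met replicate 1, and 0 without any 1 of the other 4 libraries.

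**Figure D3:**
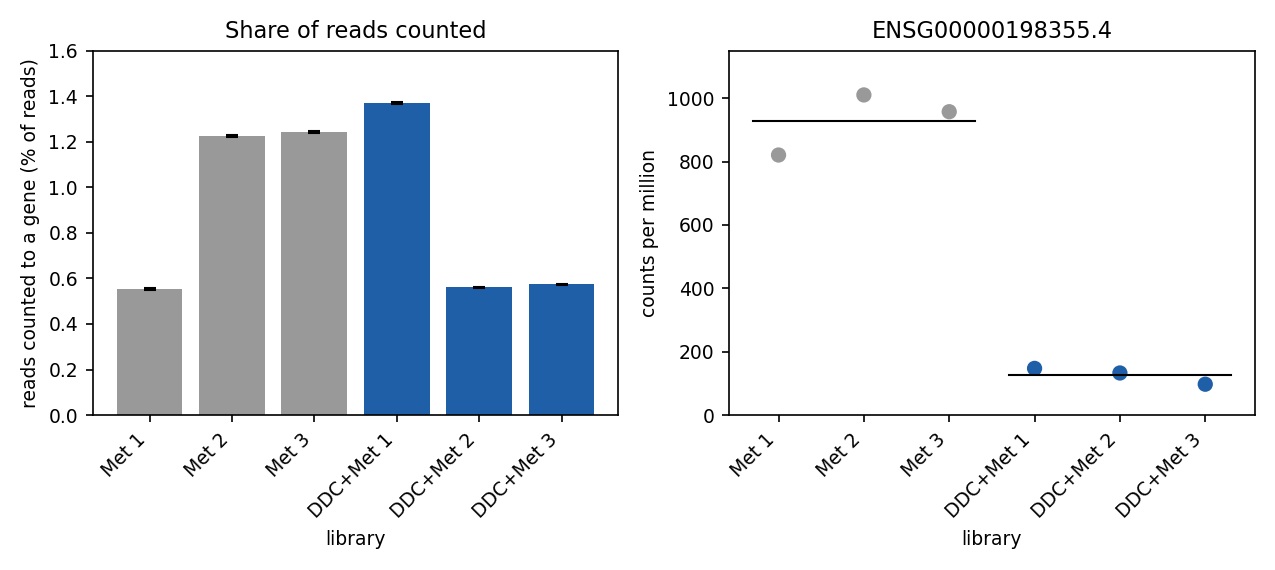
Left, the share of reads counted to a gene in each library of the diet experiment, with Wilson 95% intervals. Right, CPM of the identifier that changed, with a line at each group mean (930 in Met and 126 in DDC+Met).

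The share of reads counted did not follow the diet. Met replicate 1 and DDC+Met replicates 2 and 3 had 0.554%, 0.561% and 0.574% of their reads counted, and the other 3 libraries 1.23%, 1.24% and 1.37%. Within Met, the chi-square per degree of freedom between count profiles was 1.69 for replicates 2 and 3 and 17.1 and 17.9 for replicate 1 against them. Within DDC+Met it was 1.87 for replicates 2 and 3 and 10.7 and 12.3 for replicate 1 against them. Met replicate 1 against DDC+Met replicates 2 and 3 gave 7.51 and 7.29, and DDC+Met replicate 1 against Met replicates 2 and 3 gave 13.9 and 14.2. This measure grows with depth, and Pearson correlations of log2 CPM across identifiers, which are not independent replicates, gave another order for DDC+Met replicate 1, at 0.887 and 0.885 with Met replicates 2 and 3 and 0.852 and 0.839 with DDC+Met replicates 2 and 3. Met replicate 1 correlated at 0.890 and 0.885 with DDC+Met replicates 2 and 3 and at 0.790 and 0.779 with Met replicates 2 and 3. With the sets of low and high counted share as a term in the model, chosen after seeing the data, 63 identifiers changed, 38 higher and 25 lower, ENSG00000198355.4 among them (-2.78, SE 0.21).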

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

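Alternatives that used a library set as a term, the replicates numbered 2 and 3 alone, a set spread or a test against a fold were chosen only after the data were seen. For the diet comparison the count of 1 became 97 without a filter, 7 with a filter of 1 CPM, 31 with DESeq2, 5 with limma-voom, 63 with the low and high sets of counted shares as a term and 975 between Met and DDC+Met replicates 2 and 3 alone, where diet and counted share cannot be told apart. It ranged from 0 to 74 when a library was left out, with 74 without Met replicate 1. In the gene-strand column the 1 call was a rise, not a fall. For the EP300 comparison the count of 4851 became 2703 without a filter, 2937 with DESeq2, 1159 with 2-fold in addition, 1178 with the spread set to 20% and 480 when tested against 2-fold, and 2306 to 5154 with a library left out, the lowest without EP300 WT replicate 2 and 2602 without EP300 WT replicate 1. A lone library was then assumed to vary like the other group. The cause was not tested, except that fewer genes can pass an added fold threshold. All 2931 genes that DESeq2 shared with the 4851 kept their direction. Library size scaling gave 1846 higher and 3056 lower, against 2366 and 2485.

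Called lists numbered 19, 0 with an estimated correlation, 26 with fry and 18 to 20 with a library left out. Fry asks another question than camera, since it tests a list against no change. It did not call the immediate early list and called Notch, heme, cholesterol, fatty acid oxidation, glycolysis, lymphocyte, neutrophil and mesothelial lists in addition. Without a filter camera called 22, with fatty acid synthesis and erythroid markers lost and Notch, heme, fatty acid oxidation, neutrophil and mesothelial lists added. Macrophage markers, not called in any setting, had a median above 0 without a filter (0.010), with DESeq2 size factors and without EP300 WT replicate 1, and Met, never past the threshold, changed sign with library size alone (-0.020) and without EP300 KO replicate 2 (-0.019, against up to 0.12 with any other library left out). Of the 71 named genes, 61 kept direction and call in each of the 9 alternatives run for them. Bub1, Fdps, Gpm6a, Hk2, Klf1, Mpo, Nusap1 and Pnpla3 kept their direction but passed the threshold in some only. Limma-voom, the 1 CPM filter, the most abundant genes left out, the set spread and the test against a fold were not run for named genes. Ep300 was not past the threshold in 1 of 9 alternatives (adjusted p up to 0.128, lowest 0.000241). The replicate block gave 0 identifiers in the diet comparison and 5190 genes in the EP300 comparison. Deviations of same-numbered libraries correlated at -0.63, -0.38 and -0.43 across identifiers in the diet experiment, and at -0.00 across genes in the EP300 experiment, so the numbers do not pair the libraries and no crossed block was run. With the block 20 lists were called, without fatty acid synthesis (adjusted p = 0.0596) and with fatty acid oxidation (0.0275) and neutrophil markers (0.0291) in addition. Lists, named genes and genes carried from the diet to the EP300 comparison were not run for the diet experiment, of whose identifiers 0 matched the mouse annotation, the only one tried. At its depth, edgeR recovered 12% of simulated 2-fold changes.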

Other observations

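The families described here, from 16 examined, were chosen after the data were seen, and the signs of their medians held under all 3 scalings unless stated. In the libraries labelled EP300 KO, 72 of 80 genes with symbols of cytosolic ribosomal proteins fell and 4 rose (median -0.41, camera adjusted p = 1.94e-10, and adjusted p = 0.541 with an estimated correlation). The pseudogenes Rps3a2 and Rps3a3 are among the 80 and among those that rose. Rps3a1 fell by 1.00 while its pseudogenes Rps3a2 and Rps3a3 rose by 6.11 and 4.32, and reads can be shared among these copies. Of 12 tubulin genes, 10 fell and 0 rose (median -0.74; camera adjusted p = 1.10e-06; adjusted p = 0.192 with an estimated correlation). Of 14 carboxylesterases, 9 rose and 4 fell (median 1.06; camera adjusted p = 8.83e-16; adjusted p = 0.192 with an estimated correlation), with Ces3a at 3.75. All 19 major urinary protein genes rose. Of 38 proteasome subunits, 1 rose and 1 fell (median 0.04, and -0.02 with library size alone), and 0 of 6 MHC class II genes passed. Of 19 genes of the daily clock, 8 rose and 8 fell, with a median of 0.03 that became -0.04 with library size alone (camera upward, adjusted p = 0.0313, and adjusted p = 0.541 with an estimated correlation). Among members picked for their known phases, Arntl (-1.26) and Npas2 (-2.38, on 4 counts in the KO-labelled libraries), which peak together in mouse liver, fell, and Dbp (1.62), Nr1d1 (2.14) and Ciart (3.16), which peak at another time of day, rose. Per2 (-0.01), Cry2 (0.03) and Per3 (0.14), also clock genes, did not pass.

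Of the tests below, those of the female-biased list, the Y-linked genes, other cell types, the shares of abundant genes, the batch, the calls inside the library sets and the splits were chosen only after the result was seen. An explanation was read as excluded where its bound was met in each of the 4 pairs of a KO- and a WT-labelled library. Resampling the genes of a list was tried first as the spread, and the rule of library pairs took its place after its outcome was seen. Resampling gives wider limits, printed beside the value where genes were resampled, under which the bounds for the female-biased list and for GC content would not be met.

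Xist and male-biased liver genes were both higher in the libraries labelled EP300 KO. RNA from female mice would not raise male-biased genes, so their rise already argues against it for these genes. The test of the female-biased list therefore decides nothing more. RNA from female mice would raise that list, whose median was -1.68 (-1.89 to -1.50 over library pairs, -2.90 to -0.34 on resampling genes). For Xist, RNA from female mice stays open, since the mean of 4 Y-linked genes was -0.053 (95% interval -0.33 to 0.23), which allows a female share of up to 20.7%. Of the X-linked partners of these genes, looked at after the result was seen, Kdm5c rose (0.21, adjusted p = 0.0234) and Kdm6a (0.17), Ddx3x (0.14) and Eif2s3x (0.14) did not pass (adjusted p up to 0.320). Since these partners escape silencing in female mice, they set no bound on silencing. Their values all lie in the direction that RNA from female mice would give. X-linked genes lay below autosomal genes (difference -0.083, -0.08 to -0.05 over library pairs, -0.12 to -0.01 on resampling genes, permutation p = 0.000400), between the bounds set for silencing and for none, so silencing of the X chromosome cannot be told apart from its absence. A difference from EP300 itself may also lie behind the pattern and was not tested, as the Ep300 count did not fall.

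Fetal and tumour markers and cell cycle genes were lower in the libraries labelled EP300 KO. Removing trends on GC content and length did not take away the fall of the fetal list, on which the tests were run (median -1.59, -1.75 to -1.32 over library pairs, up to -0.16 on resampling genes). Such trends explained 0.37% of the variance of log2 fold changes, so their removal could move little. The cell cycle median after removal was -1.24. The 20 most abundant genes took 31.7% and 31.8% of the counts in the WT-labelled and 28.8% and 29.1% in the KO-labelled libraries, which can shift all other genes by at most 0.061, too little for the fall, so the median without them (-1.57) decides nothing more. Fewer cells of other types may contribute. Per the labels these are hepatocytes from sorted liver cells, but how far the sort removed other types was not measured. Markers of other types were still counted and moved both ways. Reln stood at 116 CPM in the WT-labelled and 31.9 in the KO-labelled libraries, and Gpnmb at 145 and 370. The fetal list lay below the lowest of 4 marker lists (difference -0.91), but the difference was as small as -0.44 in 1 library pair. On resampling genes it was up to 0.85. Medians were -0.28, -0.26, -0.00 and -0.67 for endothelial, stellate, macrophage and lymphocyte markers. Lists outside this test had medians of -0.62 (neutrophil), -0.74 (mesothelial, 3 genes) and 0.28 (erythroid). Immunoglobulin constant genes, a family chosen after the data were seen, had a median of -1.54 (4 of 6 fell, 0 rose). That is near the median of the fetal list (-1.58), so the gap does not hold for every marker set. A biological difference between the labelled genotypes stays open. A difference in tumour content between these libraries, titled HCC, stays open too and was not tested.

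By the share of reads counted, Met replicate 1 grouped with DDC+Met replicates 2 and 3, and DDC+Met replicate 1 with Met replicates 2 and 3, and correlations of log2 CPM across identifiers put DDC+Met replicate 1 nearer to Met replicates 2 and 3 (0.887 and 0.885) than to its own group (0.852 and 0.839), while chi-square, which grows with depth, did not (13.9 and 14.2 against 10.7 and 12.3). The counted share did not overlap between these sets (2.14 times apart), which a library batch would give. Swapped labels of the replicates numbered 1 would leave no shared diet difference inside the sets, and a batch would leave one, but these differences correlated across identifiers at r = 0.15 (rho 0.14), between the bounds of 0.1 and 0.3. With the set as a term, 63 identifiers changed along the labels, ENSG00000198355.4 among them (-2.78, SE 0.21), and 7 between both replicates numbered 1 and the rest, which runs with the labels and against a swap, yet 1 library on a side inside each set decides both counts, so a swap and a batch cannot be told apart. The 10 splits into 3 and 3 are too few for a share under 0.05, with 1 identifier called in the real split, as many or more in 2 splits counting it, and 415 in the highest other, which lies along these sets and points to a structure of the samples.

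The identifier ENSG00000105976.10 was looked up because of a gene name recalled for it, which no source used here pairs with it, so it is given by its values alone. It had the widest spread within Met of all 2066 tested, with Met replicates 2 and 3 nearly without reads. There were 2749, 4 and 4 counts in Met replicates 1, 2 and 3, and 3299, 1382 and 1488 in DDC+Met replicates 1, 2 and 3. Depth differed between the libraries, and in the same order the identifier stood at 25356, 13.6 and 13.2 CPM in Met and at 9171, 9660 and 10348 CPM in DDC+Met. Its log2 fold change was 0.21 (SE 1.95, edgeR adjusted p = 0.981). Whether these counts bear on the labels of the Met libraries, and so on the diet comparison, was left open, since no source used here names the gene.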
